A study of Mus musculus with 16 samples.

How the data were processed

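The series holds 16 mouse liver libraries in 4 groups of 4, named by their titles: negative control and AKR1B10 knockdown, each with and without BBR, read as berberine. Per the labels' protocols, poly(A) RNA was fragmented, copied with dUTP in the second strand and sequenced as 150-base pairs on a NovaSeq. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 on the mm10 build; their roles are not stated there. Per the file headers, the authors deposited whole-number counts and FPKM values per gene and library in a table of 55401 Ensembl genes. The deposited FPKM values are scaled by transcript length and library total by the authors, with 0.0001 written for every gene with a count of 0. The counting tool is not stated, and small counts fall on multiples of 4 more often than on their neighbours (760 to 1283 genes with a count of 4, against 144 to 208 with 5), so a count is not always 1 fragment and precision at low counts is below what the counts give. Whether strand was used in counting is not stated either, so antisense overlaps are uncertain. Of the gene identifiers, 99.5% are in GENCODE M21, which was used for exons and transcript sequences.

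The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The plan had assumed FPKM alone and limma on log2(FPKM + 1). Since counts were deposited, the quasi-likelihood test of edgeR 4.0.16 on the counts is the main test, chosen before either was fitted, and limma 3.58.1 on log2(FPKM + 1) is an alternative. Genes with an FPKM of at least 1 in at least 4 of the 16 libraries were tested (10846), with TMM factors, a common fit of the 4 group means to all 16 libraries, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The contrasts were the label without berberine, berberine in the negative controls, berberine in the libraries labelled knockdown, the label under berberine, and the interaction. Intervals are at 95%; those of fitted folds include the spread between mice as estimated by edgeR and no error of counting rule or annotation. Depth per library is given with the results.

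The AKR1B family was compared by exact two-sided permutation of mean FPKM (70 splits, smallest p 0.0286), outside the filter, with folds from an edgeR fit of 30801 genes. Gene lists (39, with 693 symbols, 10 of them absent from the table) were tested where at least 3 members were tested (36 lists), with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists in each contrast. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance to 1 side, were run beside it. The lists described in the text were chosen after their results were seen. A list score is the mean log2 CPM (prior count 2) of the tested members minus its mean over the 16 libraries.

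The genes named follow a rule: the AKR1B family; the genes past the threshold with the largest changes or, since fewer than 4 passed, the 8 with the smallest unadjusted p among those with groups that do not overlap (the interaction has no such condition), a mean of at least 5 FPKM in the higher group and an official symbol; and up to 4 members of each described list with the smallest p. Not all of these genes are printed.

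Alternatives were other pseudocounts, filters (none, or FPKM 5), median-of-ratios scaling, quantile normalization, fits to only the groups compared, a robust spread, library weights, the replicate number as a block, each library left out, DESeq2 1.42.0, knockdown libraries 3 and 4 left out together, and tests without mitochondrially encoded and ribosomal protein genes. The statistics were first tested on simulated counts. Identical columns were looked for and 0 pairs found. Likeness of effects was compared with 100 regroupings and with 1000 simulations of unchanged groups, and other splits of the libraries were counted (35, or 100 where more exist). Windows of 150 bases of each AKR1B transcript were searched in all other genes of the annotation. R 4.3.3 and Python 3.11.15 were used, and all 16 libraries were kept in the main analysis.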

Results

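Liver poly(A) RNA was sequenced from 16 mice in 4 groups of 4. The groups crossed a vector with a treatment. The vector was labelled AKR1B10 knockdown or negative control, and the treatment, abbreviated in the labels, was read as berberine, a plant alkaloid, from the title of the series. AKR1B10 is an aldo-keto reductase that reduces aldehydes and retinal. Total counts per library lay between 50028526 and 66235443 in the negative controls, 54570970 and 63244096 in the berberine-treated negative controls, 54764510 and 65012872 in the libraries labelled knockdown, and 46273129 and 54394727 in the libraries labelled knockdown with berberine. Mitochondrially encoded genes took 35.4% of the counts in knockdown library 4 and between 10.98% and 15.9% in the other 15 libraries.

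Akr1b10, the mouse gene with the symbol used in the label, was not lower in the libraries labelled knockdown. The gene (ENSMUSG00000061758; mm10, chromosome 6, 34384218 to 34396950, plus strand) is annotated as protein-coding with up to 10 exons. Its mean was 0.397 ± 0.151 FPKM (SD, n = 4) in the negative controls and 0.528 ± 0.230 FPKM (SD, n = 4) in the libraries labelled knockdown. With berberine the means were 0.359 ± 0.169 and 0.451 ± 0.058 FPKM (SD, n = 4 each), in the same order. The negative controls held 0.177, 0.486, 0.420 and 0.505 FPKM. The libraries labelled knockdown held 0.506, 0.351, 0.397 and 0.859 FPKM. The berberine-treated negative controls held 0.194, 0.427, 0.565 and 0.252 FPKM, and the libraries labelled knockdown with berberine held 0.527, 0.389, 0.458 and 0.427 FPKM. These levels rest on 47 to 181 counts per library. By the two-sided exact permutation test of mean FPKM, p was 0.486 without berberine and 0.371 with it (n = 4 per group), and each was 0.914 after Benjamini-Hochberg adjustment over the 16 comparisons of this gene family. The fitted ratio to the negative controls was 1.41 (95% interval 0.775 to 2.56) without berberine and 1.16 (0.637 to 2.11) with it. The sample titles name AKR1B10 and give no target sequence, so the mouse gene targeted is not known from them. Because the transcript of that name does not separate the groups, directions are given for the libraries labelled knockdown, and not for a loss of AKR1B10.

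The other family members were scarce too. Akr1b3, the mouse aldose reductase gene, had 0.420 ± 0.125 FPKM in the negative controls and 0.312 ± 0.198 FPKM in the libraries labelled knockdown (SD, n = 4). With berberine the means were 0.591 ± 0.097 and 0.343 ± 0.111 FPKM (SD, n = 4), and the groups of 4 did not overlap, with an exact permutation p of 0.0286, the smallest this design allows, and 0.229 after adjustment over the 16 comparisons. Of the 150-base stretches of its transcripts, 8.56% also occur unchanged in pseudogenes, so its counts are uncertain. Akr1b8 had means between 0.746 and 1.001 FPKM in the 4 groups, with exact permutation p-values from 0.486 to 0.886 in the 4 comparisons of n = 4 per group. Akr1b7 was listed with 0 to 25 counts per library, and its exact permutation p was 0.0286 (n = 4 per group) for berberine in the negative controls, where the means were 0.106 and 0.243 FPKM, and 0.229 after adjustment.

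**Figure D1:**
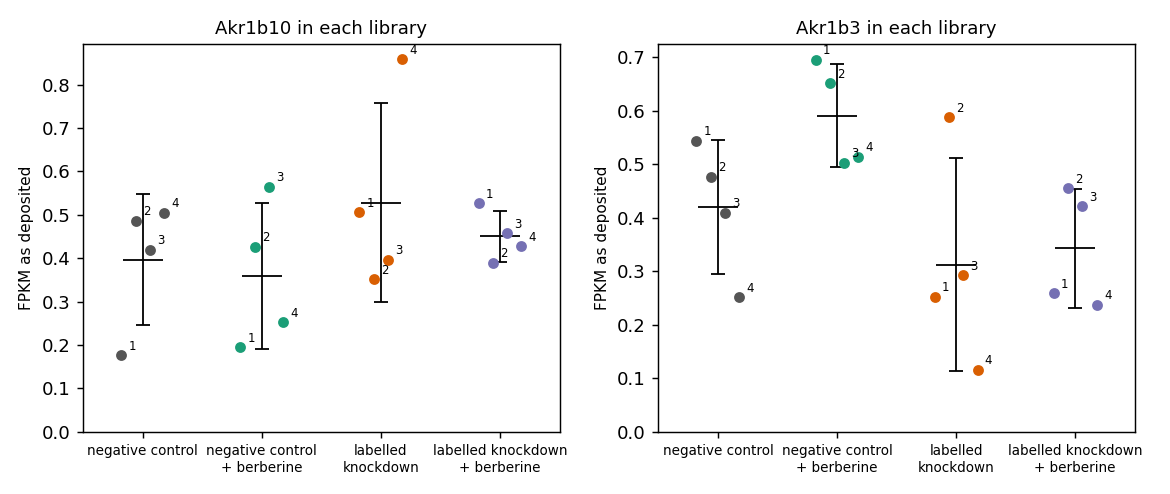
FPKM as deposited of Akr1b10 (left) and Akr1b3 (right) in each of the 16 libraries by group; points carry the library number, the horizontal line is the mean and the bar its SD. Akr1b10 lay between 0.351 and 0.859 FPKM in the libraries labelled knockdown and between 0.177 and 0.505 FPKM in the negative controls.

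The comparison of the libraries labelled knockdown with the negative controls, both without berberine, asks what the vector labelled AKR1B10 knockdown alone does to the liver. Macrophage and inflammatory transcripts were higher there and lipid-handling transcripts lower. Clec4f, a lectin of Kupffer cells, averaged 13.04 FPKM in the negative controls and 32.0 FPKM in the libraries labelled knockdown (log2 fold change 1.42, SE 0.41, n = 4 per group), and Mpeg1, a pore-forming protein of macrophages, went from 4.72 to 9.93 FPKM (1.16, SE 0.31). Cxcl1, a neutrophil attractant, averaged 3.58 and 24.3 FPKM (2.78, SE 0.70), with 64.5 FPKM in knockdown library 3, 3.12 FPKM in library 4 and 1.69 (SE 0.55) as its log2 fold change without library 3. Irf7, a regulator of interferon genes, averaged 4.46 and 8.85 FPKM (1.12, SE 0.26). In the other direction, Fads2, a fatty acid desaturase, averaged 259 and 109 FPKM (-1.15, SE 0.27), Decr1, an enzyme of unsaturated fatty acid oxidation, 71.5 and 38.6 FPKM (-0.80, SE 0.21), and Cd36, a fatty acid transporter, 25.5 and 8.28 FPKM (-1.54, SE 0.45). The fall of Cd36 was uneven, to 3.46 and 2.59 FPKM in knockdown libraries 3 and 4 and to 8.57 and 18.5 FPKM in the others. No gene passed, however: each gene named here had an adjusted p of 0.267 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

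Over all 10846 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes at an adjusted p under 0.05, and 1603 genes (903 higher, 700 lower) had an unadjusted p under 0.05. Evenly spread p-values would give 542.3, and other splits of the same libraries gave a median of 572.5. The 1603 became 2964 without knockdown library 2, 1025 without negative-control library 1, 1061 without negative-control library 2 and 945 in the fit to the groups compared. It was 394, below the 542.3 and the 572.5, with knockdown libraries 3 and 4 left out. That group is then smaller and no splits were run at its size, so the 394 does not show that the excess rests on these libraries. DESeq2 called 105 genes, 72 higher and 33 lower. Without knockdown library 2, edgeR called 609 genes, 278 higher and 331 lower, and without knockdown library 1 it called 1, 4632415L05Rik. The groups of 4 did not overlap in 529 genes, 4.88% of those tested, where chance gives 1 gene in 35 (0.0286 as a fraction, not a percent). The 8 genes of the fixed rule, those with the smallest p among genes without overlap, were C1d, Ncoa4, Irf7, Lsm14b, Myl12a, Fads2, Sdf2 and Idh2. C1d (ENSMUSG00000000581; chromosome 11, 17257579 to 17266624), a cofactor of nuclear RNA decay, had a log2 fold change of -1.84 (SE 0.33) and 7.94 against 2.11 FPKM. Ncoa4 (ENSMUSG00000056234; chromosome 14, 32159865 to 32179855), the receptor that delivers ferritin for breakdown, had -3.07 (SE 0.66) and 6.38 against 0.716 FPKM.

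As groups, 16 of the 36 gene lists tested were called by camera with a preset correlation of 0.01, 8 higher and 8 lower, and 0 were called with an estimated correlation (lowest adjusted p 0.475) or by fry (lowest adjusted p 0.172). In other splits of the same libraries the preset called a median of 12 lists, so its small p-values are also met without the real grouping. All 14 tested genes of Kupffer cells and macrophages were higher (median log2 fold change 1.10, camera adjusted p 7.78e-08, estimated-correlation adjusted p 0.475). All 12 of inflammatory cytokines and NF-kB were higher (median 1.21, camera adjusted p 1.92e-05, estimated-correlation adjusted p 0.475), as were 15 of 20 interferon response genes (median 0.45, camera adjusted p 0.00049, estimated-correlation adjusted p 0.475) and 21 of 23 acute phase genes (median 1.21, camera adjusted p 1.08e-05, estimated-correlation adjusted p 0.522). Of the 32 genes of fatty acid oxidation and PPARa targets 30 were lower (median -0.31, camera adjusted p 9.46e-07, estimated-correlation adjusted p 0.475), and of the 21 genes of lipid uptake and droplets 16 were lower (median -0.38, camera adjusted p 0.000227, estimated-correlation adjusted p 0.475). Without knockdown library 3 the median was 0.43 for the acute phase, 0.68 for Kupffer cells and macrophages and -0.16 for fatty acid oxidation, and without knockdown library 4 it was 0.28 for the interferon response. With knockdown libraries 3 and 4 left out together, the median was 0.66 for inflammatory cytokines and NF-kB and -0.23 for lipid uptake and droplets. The interferon response call was lost with a filter at FPKM 5. Mitochondrially encoded genes were higher in 13 of 13 (median 0.78, camera adjusted p 5.87e-05, estimated-correlation adjusted p 0.503), a call lost without knockdown library 4 (camera adjusted p 0.11) and with quantile normalization (0.0676). Most of their rise lay in knockdown library 4: they took 35.4% of its counts, 11.2% to 15.4% in the rest of its group and 11.0% to 13.3% in the negative controls. Markers of other cells moved too: neutrophil genes were higher in 3 of 3 (median 6.34, camera adjusted p 0.0103, estimated-correlation adjusted p 0.475) and B and plasma cell genes in 8 of 9 (median 0.74, camera adjusted p 0.00953, estimated-correlation adjusted p 0.475), and pericentral hepatocyte genes were lower in 12 of 14 (median -0.24, camera adjusted p 0.0082, estimated-correlation adjusted p 0.475). The neutrophil median hides a wide spread: the list score ran from -1.99 to 5.28 in the libraries labelled knockdown and from -2.00 to -0.48 in the negative controls. T and NK cell genes were higher in 5 of 5 (median 1.12, camera adjusted p 0.0395, estimated-correlation adjusted p 0.522), a call lost without knockdown library 1, 2 or 4 (camera adjusted p 0.0636, 0.132 and 0.102) or negative-control library 1 or 2 (0.0747 and 0.0559), and also with quantile normalization (0.093). The calls of neutrophils, B and plasma cells and pericentral hepatocytes were lost without knockdown library 3 (camera adjusted p 0.0691, 0.0691 and 0.0608), and that of B and plasma cells also without negative-control library 1 (0.0711). Within these 36 lists, 34 list members passed when adjusted over the list alone, against 0 over all genes tested; 10 of them were macrophage genes. Knockdown library 3 carried much of the acute phase difference, with 1199 FPKM of Orm2, an acute phase plasma protein, against 14.1 to 32.3 FPKM in the other libraries labelled knockdown.

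The effect of berberine in the negative controls is the comparison of the treatment alone. Serum amyloid transcripts were higher: Saa1 averaged 8.89 FPKM without and 449 FPKM with berberine (log2 fold change 5.76, SE 1.75, n = 4 per group), although 1 library, number 2 of the treated group, held 1691 FPKM and the other treated libraries 22.4 to 49.9 FPKM. Without that library the log2 fold change of Saa1 was 1.97 (SE 1.18). Lpl, the lipase that frees fatty acids from lipoproteins, averaged 2.78 and 5.20 FPKM (0.92, SE 0.26), and Fabp2, an intracellular fatty acid carrier, 187 and 113 FPKM (-0.71, SE 0.22). Clock output genes were lower: Usp2, a deubiquitinase under clock control, averaged 4.47 and 0.410 FPKM (-3.39, SE 1.14), and Bhlhe40, a clock repressor, 9.31 and 3.33 FPKM (-1.47, SE 0.53). Each of these had an adjusted p of 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so none passed.

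Of 10846 genes, edgeR's quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, with 399 genes (189 higher, 210 lower) at an unadjusted p under 0.05. Evenly spread p-values would give 542.3, but other splits of the same libraries gave a median of 297.5. The 399 became 261 without berberine-treated negative-control library 2, 612 without knockdown library 4, 654 in the fit to the groups compared, 1004 with library weights in limma voom and 657 with knockdown libraries 3 and 4 left out. DESeq2 called 3 genes, given as log2 fold changes: Irf5 (1.45, SE 0.33), Hspa1a (-3.93, SE 0.83) and E130102H24Rik (-8.12, SE 1.76). Without berberine-treated negative-control library 2, edgeR called 1 gene, Tmem254a (-14.0, SE 1.52). These few were named after their values were seen, and the sizes fitted for E130102H24Rik and Tmem254a are uncertain. The groups did not overlap in 385 genes (3.55%, by chance 1 gene in 35). Genes of the fixed rule were Txndc5 (-0.84, SE 0.20), Marveld1 (-0.72, SE 0.18), Emc9 (-0.70, SE 0.18), C1d (-1.27, SE 0.33), Fitm2 (-0.55, SE 0.14), Lpl and Tff3 (3.47, SE 0.98), given as log2 fold changes.

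Camera with the preset correlation called 22 of the 36 lists, 12 higher and 10 lower, with 0 called at an estimated correlation (lowest adjusted p 0.162) or by fry (lowest adjusted p 0.333). Without berberine-treated negative-control library 4 it called 13. Acute phase genes were higher in 22 of 23 (median 0.92, camera adjusted p 4.73e-09, estimated-correlation adjusted p 0.289), but the median was 0.28 without treated library 2 (camera adjusted p 0.0206). Cholesterol synthesis genes were higher in 22 of 25 (median 0.35, camera adjusted p 3.06e-05, estimated-correlation adjusted p 0.418). The cholesterol synthesis call rested on library 4, without which its camera adjusted p was 0.0956, the highest over its alternatives with the preset, which began at 2.69e-11. Its median was 0.16 without treated library 4, and 0.58 without treated library 2 or negative-control library 3. Cyp51, which removes a methyl group from lanosterol, averaged 17.9 and 33.7 FPKM (log2 fold change 0.91, SE 0.39). Lower were 30 of 32 genes of fatty acid oxidation and PPARa targets (median -0.27, camera adjusted p 3.06e-09, estimated-correlation adjusted p 0.273), 18 of 21 of lipid uptake and droplets (median -0.44, camera adjusted p 1.46e-07, estimated-correlation adjusted p 0.273) and 15 of 18 of the circadian clock (median -0.65, camera adjusted p 9.43e-08, estimated-correlation adjusted p 0.162). Adjusted over the list alone, 13 list members passed, against 0 over all genes.

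In the libraries labelled knockdown, the comparison of berberine with none asks whether the drug still acts under the vector labelled AKR1B10 knockdown. Sterol and fatty acid synthesis transcripts were higher with berberine. Mvd, an enzyme of the mevalonate pathway, averaged 6.07 FPKM without and 21.6 FPKM with it (log2 fold change 1.65, SE 0.52, n = 4 per group), and Lss, the lanosterol synthase, 1.16 and 3.86 FPKM (1.57, SE 0.43). Fasn, the fatty acid synthase, averaged 10.4 and 26.4 FPKM (1.17, SE 0.33). The rise was uneven, because library 4 of the treated group held 4.94 FPKM of Mvd, 1.37 of Lss and 12.3 of Fasn, near the untreated means. Hamp, the iron hormone hepcidin, was lower at 2893 and 1239 FPKM (-1.39, SE 0.36). The adjusted p of each was 0.396 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so none passed.

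Here edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 10846 genes, with 1028 (463 higher, 565 lower) at an unadjusted p under 0.05. That number was 2034 without knockdown library 2, 630 without library 2 of the knockdown libraries with berberine, 1623 with library weights in limma voom, and 670 both in the fit to the groups compared and with knockdown libraries 3 and 4 left out. DESeq2 called 55 (30 higher, 25 lower). Leaving out knockdown library 2 gave 41 genes by edgeR, leaving out knockdown library 1 gave 1 (4632415L05Rik), and leaving out berberine-treated negative-control library 2, which enters only through the shared scaling and spread, gave 1 (Usp7). The groups did not overlap in 424 genes (3.91%, by chance 1 gene in 35). The genes of the fixed rule were Lsm14b (log2 fold change 1.61, SE 0.31), Derl2 (-1.19, SE 0.24), Leng8 (1.75, SE 0.37), Mrpl14 (-1.05, SE 0.22), Edem2 (-0.52, SE 0.12), Wdr46 (0.63, SE 0.14), Nectin1 (0.73, SE 0.17) and Mir703 (-1.37, SE 0.30). Derl2 and Edem2 take part in the disposal of misfolded proteins from the endoplasmic reticulum. Mir703 counts are uncertain, because a microRNA precursor is not what a poly(A) library holds and an overlapping transcript could give them.

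Camera with the preset called 9 of the 36 lists, 6 higher and 3 lower, against 0 with an estimated correlation (lowest adjusted p 0.673) or by fry (lowest adjusted p 0.290). The 9 lie below the median of 13 lists that the preset called in other splits of the same libraries. All 25 cholesterol synthesis genes were higher (median 0.87, camera adjusted p 1.34e-15, estimated-correlation adjusted p 0.673), 11 of them past the threshold when adjusted over the list alone and 0 over all genes. Of the 21 genes of fatty acid and triglyceride synthesis, 16 were higher (median 0.28, camera adjusted p 0.000892, estimated-correlation adjusted p 0.673), and of 14 pericentral hepatocyte genes, 12 (median 0.28, camera adjusted p 0.00202, estimated-correlation adjusted p 0.673). Oat, an ornithine aminotransferase of pericentral hepatocytes, averaged 229 and 406 FPKM (log2 fold change 0.67, SE 0.18). Acute phase genes were lower in 22 of 23 (median -1.06, camera adjusted p 1.54e-05, estimated-correlation adjusted p 0.919). That call rested on knockdown library 3, without which the camera adjusted p was 0.352, the highest over its alternatives with the preset, which began at 3.71e-11, and the median was -0.23. For fatty acid and triglyceride synthesis the median was 0.52 without library 4 of the knockdown libraries with berberine. With knockdown libraries 3 and 4 left out, the pericentral median was 0.14 and its call was lost.

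Under berberine, the libraries labelled knockdown were compared with the negative controls, which asks whether the vector matters in treated mice. Heat shock transcripts were higher in the libraries labelled knockdown. Hspa8, a constitutive chaperone, averaged 177 and 385 FPKM (log2 fold change 1.07, SE 0.22, n = 4 per group), and Hspa1a, its inducible relative, 0.270 and 2.85 FPKM (3.31, SE 0.97). Jun, an immediate early transcription factor, averaged 4.27 and 30.3 FPKM (2.80, SE 0.79), with 100.4 FPKM in library 3 of the higher group and 4.03 to 10.8 FPKM in the others. Without that library its log2 fold change was 0.61 (SE 0.31). Got1, a transaminase of the malate-aspartate shuttle, was lower at 97.97 and 40.4 FPKM (-1.35, SE 0.36), and Angptl8, a liver hormone that restrains lipoprotein lipase, was higher at 19.8 and 79.3 FPKM (1.95, SE 0.52). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.679 for Hspa8 and 0.995 for the others, so none passed.

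That test called 0 of 10846 genes after Benjamini-Hochberg adjustment (edgeR), with 496 (258 higher, 238 lower) at an unadjusted p under 0.05. Evenly spread p-values would give 542.3, but other splits of the same libraries gave a median of 298. The 496 became 286 without berberine-treated negative-control library 2, 750 without library 4 of the same group, 795 without knockdown library 4, 774 in the fit to the groups compared, 1041 with library weights in limma voom and 850 with knockdown libraries 3 and 4 left out. DESeq2 called 5, named after their values were seen and given as log2 fold changes. Higher were Hspa8 (1.06, SE 0.22), Txndc5 (1.06, SE 0.21) and Zbtb40 (1.01, SE 0.22). Falls were fitted for Krt5 (-22.3, SE 3.13) and Commd1b (-25.4, SE 4.21). Folds of that size cannot be measured at these depths, so they are not to be read as measured falls, and edgeR called neither gene. Without berberine-treated negative-control library 2 edgeR called 1, Tmem254a (13.96, SE 1.52), again of uncertain size. The groups did not overlap in 498 genes (4.59%, by chance 1 gene in 35). The fixed rule gave Txndc5 (log2 fold change 1.06, SE 0.20), Hspa8, Lpl (-1.06, SE 0.26), Entpd8 (0.81, SE 0.21), Got1, Angptl8, Sgf29 (0.51, SE 0.14) and Mup-ps22 (-1.83, SE 0.45). Mup-ps22 belongs to the near-identical major urinary protein family, so its counts are uncertain.

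Of the 36 lists, 9 were called by camera with the preset, 5 higher and 4 lower, and 0 with an estimated correlation (lowest adjusted p 0.167) or by fry (lowest adjusted p 0.299). The median over other splits of the same libraries was 12 lists with the preset, above the 9. The preset called 15, 16 and 14 lists without berberine-treated negative-control library 1, 3 or 4. All 12 immediate early and heat shock genes were higher (median 1.36, camera adjusted p 5.89e-10, estimated-correlation adjusted p 0.167), 7 of them past the threshold when adjusted over the list alone and 0 over all genes. Also higher were 15 of 18 circadian clock genes (median 0.65, camera adjusted p 3.86e-06, estimated-correlation adjusted p 0.173) and 19 of 21 genes of fatty acid and triglyceride synthesis (median 0.35, camera adjusted p 0.000153, estimated-correlation adjusted p 0.504). Acute phase genes were lower in 23 of 23 (median -0.87, camera adjusted p 3.86e-06, estimated-correlation adjusted p 0.657), a call that rested on berberine-treated negative-control library 2. Without that library the camera adjusted p was 0.440, the highest over its alternatives with the preset, which began at 4.55e-09, and the median was 0.026, on the other side of 0. Medians also shrank for immediate early and heat shock genes, to 0.47 without library 3 of the knockdown libraries with berberine, for the circadian clock, to 0.33 without library 4 of that group, and for fatty acid and triglyceride synthesis, to 0.22 without berberine-treated negative-control library 2.

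Whether the berberine effect differed between the libraries labelled knockdown and the negative controls was tested as an interaction. Acute phase transcripts went in opposite directions, higher with berberine in the negative controls and lower in the libraries labelled knockdown, mostly through berberine-treated negative-control library 2 and knockdown library 3. Orm2 had an interaction of -9.19 (log2, SE 2.38), Saa1 of -8.94 (SE 2.32) and Lcn2, an iron-trapping protein of inflammation, of -8.68 (SE 2.35). Without library 2 of the treated negative controls these were -5.47, -5.13 and -4.85, and without knockdown library 3 -5.50, -5.59 and -5.07. Lipid synthesis went the other way: Fasn had 1.65 (SE 0.46) and Lpin1, a phosphatase of triglyceride synthesis, 4.36 (SE 1.32). Lpin1 stood at 7.48 and 16.2 FPKM in negative-control libraries 2 and 3, but at 0.461 and 0.997 FPKM in libraries 1 and 4, within the 0.248 to 1.13 FPKM of the treated negative controls. The adjusted p of each was 0.756 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, so none passed.

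edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes for this interaction, with 711 (294 higher, 417 lower) at an unadjusted p under 0.05, a number that was 1538 without knockdown library 2, 463 without berberine-treated negative-control library 2 and 1326 with library weights in limma voom. DESeq2 called 10. Without knockdown library 1 edgeR called 1, 4632415L05Rik (log2 4.85, SE 0.30). Without berberine-treated negative-control library 2 it called 1, Tmem254a (14.1, SE 1.66), its size again uncertain. The fixed rule named C1d (2.23, SE 0.46), Derl2 (-1.41, SE 0.33), Lsm14b (1.79, SE 0.43), Zfyve21 (-1.84, SE 0.45), Lpl (-1.49, SE 0.36), Nectin1 (0.94, SE 0.24), Orm2 and Mup-ps22 (-2.53, SE 0.62). Camera with the preset called 19 of the 36 lists, 10 higher and 9 lower, against 0 with an estimated correlation (lowest adjusted p 0.260) or by fry (lowest adjusted p 0.217). Other splits of the libraries gave a median of 12 lists with the preset. All 23 acute phase genes had a negative interaction (median -1.91, camera adjusted p 9.01e-13, estimated-correlation adjusted p 0.309), 16 of them past the threshold when adjusted over the list alone and 0 over all genes. Positive were 18 of 21 genes of fatty acid and triglyceride synthesis (median 0.82, camera adjusted p 1.07e-07, estimated-correlation adjusted p 0.260), 29 of 32 of fatty acid oxidation and PPARa targets (median 0.38, camera adjusted p 3.6e-07, estimated-correlation adjusted p 0.370), 11 of 12 immediate early and heat shock genes (median 1.43, camera adjusted p 2.69e-05, estimated-correlation adjusted p 0.260) and 16 of 18 circadian clock genes (median 0.85, camera adjusted p 0.000342, estimated-correlation adjusted p 0.260). Without library 3 of the knockdown libraries with berberine the immediate early and heat shock median was 0.18, without library 4 of that group the clock median was 0.38, and without knockdown library 3 the medians of the acute phase and of fatty acid oxidation were -1.16 and 0.22.

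**Figure D2:**
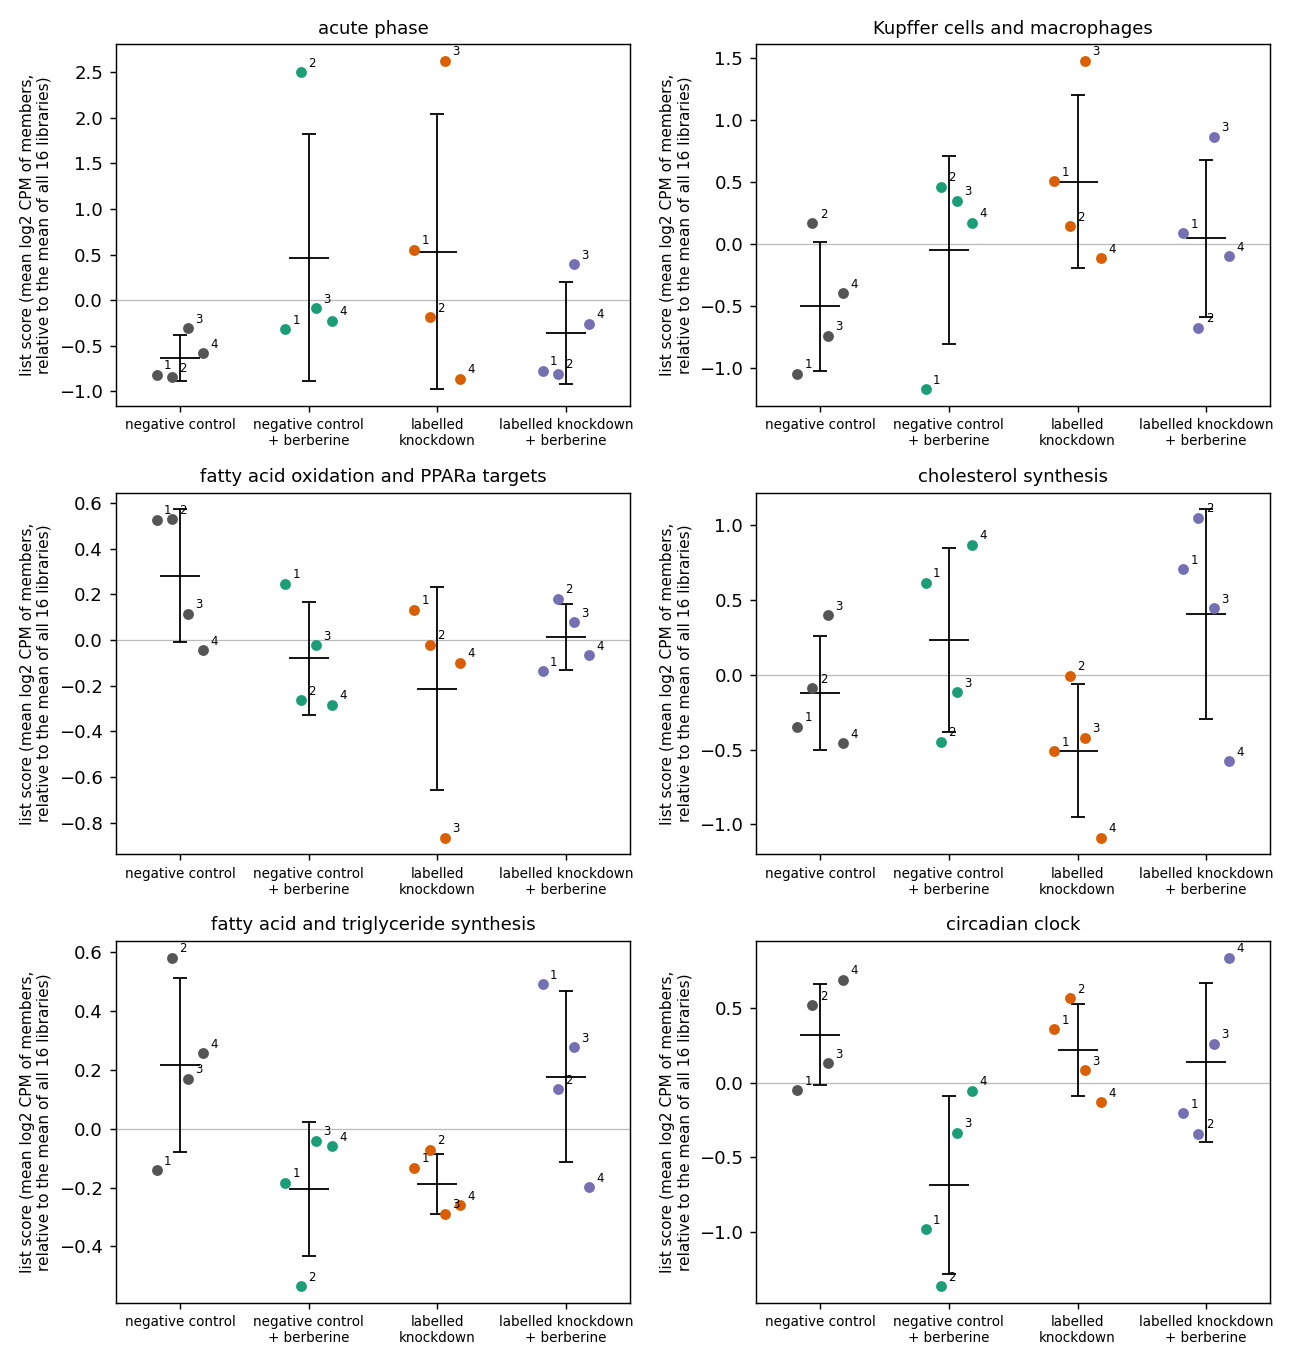
Scores of 6 gene lists in each of the 16 libraries by group (mean log2 CPM of the tested members, minus the mean over the 16 libraries); points carry the library number, the horizontal line is the group mean and the bar its SD. The acute phase score was 2.50 in library 2 of the berberine-treated negative controls and 2.63 in library 3 of the libraries labelled knockdown, and at most 0.55 in the others.

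Across genes, the berberine effect in the negative controls and that in the libraries labelled knockdown did not resemble each other. Over 10846 genes, which are not independent replicates, the Pearson correlation of the fold changes was -0.139, the Spearman correlation -0.092 and the covariance -0.033, and 46.2% of genes had the same sign in both. In 100 regroupings of the libraries within each vector the Pearson correlation ran from -0.317 to 0.287, and 46 lay at least as far from 0. The title of the series names AKR1B10 as a target of berberine, so the effect of the label without berberine was also set beside that of berberine in the negative controls. These effects share the 4 negative controls. The Pearson correlation of the fold changes across genes was 0.491 and the Spearman correlation 0.405. On log2 CPM the Pearson correlation was 0.411 and the covariance 0.101, against simulated means of 0.489 and 0.102 with no effect, a covariance difference of -0.0007. The central 95% of those simulations was wide, from 0.106 to 0.739 for the Pearson correlation and from 0.018 to 0.191 for the covariance. With the controls split 2 and 2 in the 6 possible ways, the Pearson correlation ran from 0.003 to 0.171, with a mean of 0.095, which 23.9% of 1000 simulations with no effect reached (mean -0.012, central 95% from -0.370 to 0.254). The covariance averaged 0.029 over these splits, which 22.3% of the simulations reached, drawn from all 16 libraries as before. A likeness beyond that of the shared controls was not shown, and it is not excluded.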

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

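In this part, the interval tests on Akr1b10 and the muscle test were chosen after the results they measure had been seen. The other tests of explanations were written down before they were run. The libraries that some of them name had been picked from results already seen. For each library measure, each gene of the naming rule and each described list, the highest or lowest library of each group of 4 was set against the rest of its group. Of 452 groups tested, 45 held a library far from its group by Dixon's test on FPKM, where chance gives about 1 in 20. With the genes on log2 CPM it was 27 groups, near what chance gives, so the excess depends on the scale.

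The transcript named by the label, Akr1b10, was not lower in the libraries labelled knockdown. The tables argue against reads shared with its paralogs, because 0 of the 3584 windows of 150 bases in its transcripts occur unchanged in another gene (0%). Averaged over both treatments the fold was 1.28 with a 95% interval whose lower bound was 0.837. This argues against too few counts to see a fall to 0.5 of the control level. Too few counts are not excluded, since the interval includes no error of the counting rule or of the labels. A swap of whole groups after a fall to 0.5 or less would put the averaged fold at 2 or more, and the upper bound was 1.95, close to that limit; a swap after a smaller fall stays open. Also open, and untested, are a knockdown that acts on the protein, in few cells or on another sequence than the counted transcript, which includes another gene of the family.

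Knockdown library 2 sets how many genes pass for the label without berberine: 0 with it and 609 without it by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over all genes tested, it correlated better with the mean of the negative controls (0.972) than with the other 3 libraries labelled knockdown (0.940), a difference of 0.0323. Between these 2 groups, each of the other 7 libraries correlated better with its own. With all 4 groups compared, however, other libraries were also closest to a group that was not theirs. Among them was negative-control library 4, at 0.966 with the libraries labelled knockdown with berberine and 0.963 with its own group. So were libraries 3 and 4 of the treated negative controls and libraries 2 and 4 of the libraries labelled knockdown with berberine. The pattern of knockdown library 2 is what a wrong label on it would give, and also what a mouse that did not respond would give. An exchange with negative-control library 4 cannot be told apart from that library's spread, since its correlation with the knockdown mean minus that with the rest of its own group was only -0.00324; the exchange is the split that called 559 genes. Knockdown library 2 correlated at 0.948 with that library and at 0.956 to 0.959 with the other negative controls. Part of the low correlation with its own group may come from knockdown libraries 3 and 4, which stand apart themselves, and no biological explanation was tested beyond the label.

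The acute phase list moved in opposite directions with berberine in the negative controls and in the libraries labelled knockdown. High levels in berberine-treated negative-control library 2 and knockdown library 3, a pair picked after their values were seen, account for most of its size. Without both, the median interaction went from -1.91 to -0.58 (log2). That of Orm2, Saa1 and Lcn2 went to -1.77 (SE 0.94), -1.78 (SE 0.92) and -1.24 (SE 0.93), each at an adjusted p of 0.946 by edgeR's quasi-likelihood test. The list was still called with the same sign by camera with the preset (adjusted p 0.000489), though not with an estimated correlation (adjusted p 0.684). Because the preset called a median of 12 lists in other splits for the interaction, that call does not settle whether anything is left. The fall with berberine in the libraries labelled knockdown was no longer called (median -0.22, camera adjusted p 0.176). Muscle RNA is excluded as a source shared by both libraries, because the muscle score of knockdown library 3 was 1.16, within the -3.05 to 1.55 of the 14 libraries left. An acute phase response of single mice, to infection, injury or handling, stays open and untested.

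Berberine-treated negative-control library 2 held 750.1 FPKM of Orm2, 152 of Lcn2, 1691 of Saa1, 1522 of Saa2, 21.3 of Orm3, 442 of Serpina3n and 24.8 of Tff3, all far above its group. Its Bhlhe40 was low at 2.101 FPKM, its acute phase score was 2.50 and its TMM factor was low at 0.947. Knockdown library 3 was far above its group for the acute phase genes Orm2 (1199 FPKM), Lcn2 (313 FPKM), Saa1 (867 FPKM), Saa2 (552 FPKM) and Orm3 (60.9 FPKM), and for Csf1r (8.12 FPKM) and Edem2 (23.4 FPKM). Knockdown library 4 gave 35.4% of its counts to mitochondrially encoded genes, against 11.2% to 15.4% in its group, and 49.3% to its 20 highest genes, against 26.98% to 30.3%. It held 175 FPKM of Angptl8, far above its group, and 5.01 FPKM of Marveld1, far below. In knockdown library 2, Ncoa4 (1.5986 FPKM), Lsm14b (4.004 FPKM) and Lpin1 (1.402 FPKM) were far above the other libraries labelled knockdown.

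Among the negative controls, library 4 was low for Ncoa4 (2.92 FPKM) and Myl12a (8.23 FPKM) and high for Orm2 (12.1 FPKM). Library 2 was high for Idh2 (34.9 FPKM) and Noct (4.44 FPKM), library 3 was high for Tff3 (2.001 FPKM) and Sqle (7.99 FPKM), and library 1 was low for Saa1 (6.29 FPKM). Of the berberine-treated negative controls, library 1 was high for Decr1 (77.7 FPKM) and low for Lpin1 (0.248 FPKM), library 3 was high for Hspa1a (0.747 FPKM) and for genes with a count above 0 (22241), and library 4 was low for Myl12a (8.75 FPKM) and Derl2 (6.87 FPKM). In the libraries labelled knockdown with berberine, library 1 was high for Angptl8 (140.6 FPKM), library 2 for Decr1 (65.96 FPKM), library 3 for Orm3 (3.02 FPKM), Jun (100.4 FPKM) and Akr1b7 (0.27 FPKM, the others listed at 0 counts), and library 4 for Ciart (12.6 FPKM), while Got1 was low in library 4 (30.1 FPKM).

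The berberine effect differed between the negative controls and the libraries labelled knockdown in 19 lists by the interaction test of camera with the preset, and in 0 with an estimated correlation (lowest adjusted p 0.260). Beside the acute phase (adjusted p 9.01e-13), the list was more positive in the libraries labelled knockdown for fatty acid and triglyceride synthesis (adjusted p 1.07e-07), fatty acid oxidation and PPARa targets (3.6e-07), glycolysis and glycogen (8.06e-06), lipid uptake and droplets (2.44e-05), immediate early and heat shock (2.69e-05), circadian clock (0.000342), cholesterol synthesis (0.000342), other aldo-keto reductases (0.00308), NRF2 targets (0.0098) and white fat (0.0364). It was more negative for Kupffer cells and macrophages (1.31e-06), neutrophils (0.00733), inflammatory cytokines (0.0098), muscle (0.0202), mitochondrially encoded genes (0.0207), interferon response (0.0364), fibrosis and stellate cells (0.0364) and cholangiocytes (0.042), all as camera adjusted p-values.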

How the results depend on the processing

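The alternatives chosen after the data were seen are DESeq2, knockdown libraries 3 and 4 left out together, and the tests without mitochondrially encoded and ribosomal protein genes. limma on log2(FPKM + 1), the main test as first planned, became an alternative when counts were found, before either was fitted. The other alternatives were written down beforehand.

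No described list changed its direction by camera under any alternative run, but the median of the acute phase list under berberine went from -0.87 to 0.026 without berberine-treated negative-control library 2. With camera at an estimated correlation, and with fry, 0 lists were called in each of the 5 comparisons, against 16, 22, 9, 9 and 19 with the preset. A filter at FPKM 5 took the lists called for berberine in the negative controls from 22 to 13 and ended the interferon response call for the label without berberine (adjusted p 0.344 with 5069 genes tested, against 2.16e-05 at the lowest of its alternatives with the preset). Without a filter, berberine in the libraries labelled knockdown called 16 lists in place of 9. With knockdown libraries 3 and 4 left out, the pericentral call for berberine in the libraries labelled knockdown was lost (adjusted p 0.0907, from 5.43e-05 at the lowest; the cause was not tested), as were, for the label without berberine, those of neutrophils (0.198), B and plasma cells (0.0911) and pericentral hepatocytes (0.0911). Without mitochondrially encoded and ribosomal protein genes, 15, 22, 8, 9 and 18 lists were called, all among those called with them.

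The number of genes past the threshold was 0 by edgeR in all 5 comparisons, with 1603, 399, 1028, 496 and 711 at an unadjusted p under 0.05, 2558, 1177, 1846, 1317 and 2062 of 30801 with no filter, and 916, 196, 601, 215 and 387 of 5069 at FPKM 5. DESeq2 called 105 for the label without berberine, 3 for berberine in the negative controls, 55 for berberine in the libraries labelled knockdown, 5 for the label under berberine and 10 for the interaction; the cause was not tested. Of its 105 genes, 92 were among the 609 called without knockdown library 2. Library weights with limma voom called 4 for the label without berberine (C1d, Pacsin2, Zfp281, Oas1g), and the fit to only the libraries compared called 1 for berberine in the negative controls (C1d). Without knockdown libraries 3 and 4, 1 gene (AW146154) was called for the label, for berberine in the libraries labelled knockdown and for the interaction. limma on log2(FPKM + 1) or log2(FPKM + 0.1) called 0 throughout; they moved the median of all genes by -0.10 and -0.13 for the label, 0.14 and 0.18 for berberine in the libraries labelled knockdown, and 0.15 and 0.20 for the interaction.

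Leaving out each library in turn gave 0 to 609 genes for the label without berberine, 0 to 41 for berberine in the libraries labelled knockdown and 0 to 1 in the other comparisons. The libraries behind this were knockdown library 2 (609 and 41), knockdown library 1 (1) and berberine-treated negative-control library 2 (1). For lists, it gave 13 to 22 for berberine in the negative controls, lowest without treated library 4, and 8 to 16 for the label under berberine, with 15, 16 and 14 without treated negative-control library 1, 3 or 4. The calls lost are given with the comparisons. Of the named genes outside the AKR1B family, only Orm2 under berberine changed sign, from -3.44 to 0.29 without berberine-treated negative-control library 2 (range -4.18 to 0.29).

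The AKR1B genes, none of them called, changed sign as follows (log2). For the label without berberine, Akr1b8 (0.016) became -0.0056 with limma at a pseudocount of 0.1, -0.015 at 1, -0.083 with quantile normalization, -0.015 in the fit to the libraries compared and -0.13 without knockdown libraries 3 and 4, with a leave-one-out range of -0.20 to 0.37; Akr1b3 became 0.069 without those libraries, and Akr1b7 0.12 with the replicate block. For berberine in the libraries labelled knockdown, Akr1b3 (-0.0066) became 0.19 and 0.042 with limma at a pseudocount of 0.1 and 1, 0.0037 with median-of-ratios scaling, 0.19 with quantile normalization, 0.0068 in the fit to the libraries compared, 0.059 with library weights, 0.12 with the replicate block and 0.0031 with DESeq2 (leave-one-out -0.27 to 0.52), and Akr1b7 ran from -5.75 to 0.11. In the interaction, library weights gave -0.14 for Akr1b8 (0.09, leave-one-out -0.26 to 0.32) and 0.12 for Akr1b10 (-0.28, leave-one-out -0.49 to 0.10), and Akr1b10 was 0.036 without knockdown libraries 3 and 4. Leave-one-out also ran from -0.38 to 0.10 for Akr1b10 with berberine in the negative controls, from -0.094 to 0.33 for Akr1b8 under berberine, and from -0.76 to 0.033 for Akr1b3 in the interaction.

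The replicate block called 0 genes in all comparisons and 16, 21, 9, 10 and 17 lists. The numbers do not pair the libraries: same-numbered libraries correlated at a median of 0.008, over 0.1 in 4 of 24 pairs, and 5 of 16 libraries correlated best with their own number.

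In counts simulated at these depths for the label without berberine (10846 genes, 200 changed), edgeR recovered 31% of genes changed 2-fold, 83.5% of those changed 4-fold and 95.5% of those changed 8-fold, with 6 to 8 false calls.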

Other observations

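The tests of opposite clock genes, of cholesterol synthesis and AKR1B genes averaged over groups, and of muscle genes were chosen only after the results were seen.

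Other splits of the same libraries were used to ask whether chance can be excluded. Where the real split called 0 genes, every split reaches that number, so the count of genes past the threshold tells nothing about chance in any of these comparisons. For the label without berberine that was 35 of 35 splits by edgeR, and the highest of the others gave 559, the split that exchanges knockdown library 2 with negative-control library 4; a split that calls so many points to a structure of the samples other than their labels. For genes at an unadjusted p under 0.05 (1603), 3 of 35 splits gave as many, highest other 3034, and for lists (16), 6 of 35, highest other 18, so chance is not excluded for these numbers. Berberine in the negative controls gave 0 genes in the real split and at most 1 in another, so that 35 of 35 gave as many. It gave 399 at an unadjusted p under 0.05 (9 of 35, highest other 582) and 22 lists, a number that 1 of 35 splits reached, the real split, against a highest other of 17. That share, 0.0286, is the smallest that 35 splits can give. It is 1 of 12 such counts read without allowance for their number, so chance is not excluded for it. The 22 fell to 13, under the highest other, without treated negative-control library 4 and also with a filter at FPKM 5.

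Berberine in the libraries labelled knockdown gave 0 genes (35 of 35 splits, highest other 2), 1028 at an unadjusted p under 0.05 (7 of 35, highest other 2124) and 9 lists (32 of 35, highest other 20). The label under berberine gave 0 genes (35 of 35, highest other 1), 496 (7 of 35, highest other 859) and 9 lists (27 of 35, highest other 19). The interaction, with 100 splits, gave 0 genes (100, highest other 1), 711 (20, highest other 1498) and 19 lists (7, highest other 21). Chance is not excluded for the numbers above 0.

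Averaged over both vectors, berberine gave 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p 0.658) and 644 at an unadjusted p under 0.05. Of 100 splits within each vector, 100 and 28 gave as many, with highest others of 5 and 1894. Every split reaches a count of 0, so for both averages that count again tells nothing about chance. Averaged over both treatments, the label gave 0 genes (lowest adjusted p 0.304; 100 of 100 splits, highest other 2) and 1310 at an unadjusted p under 0.05, which 3 of 100 splits reached (highest other 1736). That share, 0.03, has no allowance for the 12 counts read, so chance is not excluded for that last number. With 1 library left out it ran from 931 (negative-control library 1) to 2364 (knockdown library 2), above the median of 403 in other splits of all libraries. It was 665 with knockdown libraries 3 and 4 left out together, library 4 being the one with 35.4% mitochondrially encoded counts. What the number reflects stays open. edgeR called 81 genes for the averaged label without knockdown library 2. For either average it called 1 gene, named after its values were seen, without knockdown library 1 (4632415L05Rik), berberine-treated negative-control library 2 (Tmem254a) or knockdown libraries 3 and 4 (AW146154), and the 644 for berberine was 1074 without knockdown library 2. DESeq2 was not run on these averages. Akr1b3 had an averaged fold of 0.651 (95% interval 0.438 to 0.967; exact stratified permutation p 0.0265, n = 4 per group, not adjusted over the 4 genes of its family) in the libraries labelled knockdown. Akr1b7, at 0 to 25 counts per library, had 0.449 (0.110 to 1.83; exact p 0.0498, edgeR unadjusted p 0.246).

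A hypothesis from the clock genes is that the libraries differ in clock phase. Arntl, Npas2, Cry1 and Nfil3 peak opposite to Dbp, Tef, Per2, Per3, Ciart and Usp2, and the means of these sets (log2 of FPKM + 0.1) correlated over the 16 libraries at r = -0.905 and rho = -0.903 (permutation p 1e-05 for both, the smallest 100000 resamples can give; 3e-05 after Benjamini-Hochberg adjustment over 6 relations). Centred by group, r was -0.894 and rho -0.912, and without the libraries farthest from the median -0.854. Dbp ran from 0.572 FPKM in berberine-treated negative-control library 2 to 80.1 FPKM in negative-control library 4. This is consistent with mice killed at different clock times or with shifted clocks, which were not told apart here. The phase score was higher with berberine by 2.19 averaged over both vectors (exact stratified permutation p 0.0245, n = 4 per group, unadjusted): 3.11 in the negative controls and 1.27 in the libraries labelled knockdown.

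A further hypothesis is that berberine raises cholesterol synthesis transcripts whatever the vector. The list score was higher by 0.63 (log2) averaged over both vectors, by 0.35 in the negative controls and 0.91 in the libraries labelled knockdown, with an exact stratified permutation p of 0.042 over 4900 regroupings (n = 4 per group) and 0.489 after Benjamini-Hochberg adjustment over the 36 lists, which it fails. The retinoid metabolism and pericentral lists had smaller unadjusted p-values (0.0171 and 0.0245, each 0.441 after adjustment). It may be tied to clock phase: phase and cholesterol synthesis scores correlated at r = 0.447 (permutation p 0.0833) and rho = 0.512 (p 0.046, 0.0689 after Benjamini-Hochberg adjustment over 6 relations), and at r = 0.615 without the libraries farthest from the median. Centred by group, they correlated at r = 0.295 (permutation p 0.266) and rho = 0.241 (p 0.366), and -0.149 without the libraries farthest from the median, so the data do not settle it. The acute phase score correlated with fatty acid oxidation at r = -0.683 (permutation p 0.00486, rho = -0.429) and with lipid uptake at r = -0.564 (p 0.0212), and at -0.227 and -0.226 without knockdown library 3 and berberine-treated negative-control library 2.

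Skeletal muscle RNA is a candidate source of transcripts in berberine-treated negative-control library 2. All 12 muscle genes on the list reached their highest FPKM there; Acta1 stood at 70.3 FPKM against at most 1.76 FPKM elsewhere, Tnnc2 at 48.5 against 1.61 and Ckm at 20.01 against 0.986. Only 3 of the 12 passed the expression filter, and these moved by a median of 5.15 (log2) with berberine in the negative controls (camera adjusted p 0.0406, estimated-correlation adjusted p 0.414). That move rests on library 2. The muscle score was 6.01 there and at most 1.55 in any other library, and it went down to -2.58 in the treated group and -2.88 in the negative controls.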
